A study of Drosophila melanogaster with 3 samples.

How the data were processed

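Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole wandering larvae of Drosophila melanogaster, males and females pooled. The flies carried an artificial exon encoding eGFP in an intron of fru, so that the endogenous gene makes a GFP fusion protein, and chromatin was precipitated with an anti-GFP antibody. Chromatin was sonicated, with fragments of 200 to 800 bp per the labels. The 3 biological replicates form 1 group, so no comparison between conditions was possible. A control experiment is named in the labels and was not analysed here. Reads and signal tracks were not used here.

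The deposited lists give regions with a summit position and a signal value, which is a score with no fixed range made by the authors from alignments of the ChIP reads together with a control alignment, per the sample notes deposited with the lists. The aligner, the peak caller, its settings and the cutoff of the irreproducible discovery rate (IDR) are not given in the sources used here. Each replicate has a list of 30000 regions called peaks and background, meant as input for the IDR step, and a further list of 30000 regions comes from the pooled reads. A thresholded list of 8996 regions was derived by the authors from these lists. Every region of the thresholded list is one of the 8996 of highest signal value in the pooled list, as checked on the values. The signal value is the authors' own and was used to describe, rank and filter regions within 1 list, never to compare levels between lists. Each list exists on 2 genome builds, dm6 and dm3; positions are given 1-based on dm6, and no position was converted between builds.

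Genes, transcription start sites (TSSs) and transcript parts came from the Ensembl annotation of BDGP6.54, release 115, which has the coordinates of dm6; all regions lay within its chromosome lengths. Pseudogenes and transposable elements were left out. Chromosomes 2L, 2R, 3L, 3R, 4, X and Y were analysed. Listed gene symbols were matched to current ones, by synonym where needed. The symbols Hsrw and lncRNA:Hsromega matched no protein-coding gene and were left out, and the entries Bearded, don-juan, Dpt and ebony were left out because they matched no current symbol.

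The tests, gene lists, words, naming rule and alternatives were chosen before the data were examined. To put replicates on an equal footing, the 8996 strongest regions of each replicate list were taken. Regions of a pair of lists were called shared when their summits lay within 100 bp, and the shared count was set against 1000 random circular shifts of 1 list along each chromosome, one-sided. Presence of a thresholded peak in a replicate used the same distance. Spearman correlations of signal values were computed across shared peaks, without a p-value. Each thresholded summit was assigned to the first feature it met in the order promoter (within 500 bp of a TSS), 5' UTR, coding sequence, 3' UTR, other exon, intron and intergenic. Shares were compared with 1000 circular shifts and, by Fisher's exact test, with the pooled input regions that did not pass the threshold. Chromosome shares were compared with the same regions by Fisher's exact test.

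A protein-coding gene counted as having a peak when a thresholded summit lay within 500 bp of any of its TSSs. The 24 gene lists were each compared with all other protein-coding genes by a two-sided Fisher's exact test, and with 10000 random lists matched on gene length and number of TSSs. The share of summits with each of 12 words on either strand within 50 bp was compared with windows centred 500 bp away by an exact McNemar test, which used 1 side per peak drawn at random, and all 6-mers were tested the same way. The words were also compared with summits of the pooled input regions that did not pass, by Fisher's exact test. Odds of a word are the peaks with it under the summit alone divided by those with it in the flank alone, with the same small constant added to both counts. Flank shares of the 12 words are means over both sides. All p-values are two-sided unless stated and were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. Intervals on shares are 95% Wilson intervals. They cover the sampling of peaks or genes only, and neighbouring peaks are not independent.

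The genes named are those nearest to the 25 peaks of highest signal value, and fru with its peaks. In each list past the threshold by Fisher's exact test, up to 6 members with the strongest peak at a TSS and up to 2 without one, alphabetically, are named. In other lists these numbers are up to 3 and up to 1. The genes dsx, tra, lola, robo1, Sxl and tei are named whatever their values.

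Alternatives were a summit distance of 250 bp, region overlap by 50% of each or by 1 bp, whole replicate lists, the strongest 4498 regions of each list, and the other build. Further alternatives were peaks present in all 3 replicates, peaks present in both remaining replicates after leaving out each replicate in turn, and promoters of 250 or 1000 bp. Leaving out a replicate only filtered the authors' thresholded list. That list was not called anew and still rests on the pooled reads, those of the left-out replicate included. The regions that did not pass stayed the same. Gene lists were also tested with a summit anywhere in the gene or within 1000 bp of it, and against genes with an input region at a TSS. Words were also tested within 25 or 100 bp of the summit and with flanks 1000 bp away. Families of genes and words of 8 bases were added after the main results were seen and are described under other observations.

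The overlap, feature, gene-list and 6-mer tests were first run on simulated data. The chromosome test and the comparison of words with regions that did not pass, both Fisher's exact tests, were not simulated. Lists with 0, 20 and 60% of 8996 regions planted as shared gave shares of 1.49, 21.3 and 60.6%. For promoters, a planted share of 40.2% came back as 40.2%. Among unchanged lists of 20, 40 and 90 genes, 3.5, 4.5 and 4.5% had a Fisher p under 0.05, and lists with 0.5 of their genes bound were found in 100% of draws. Bound genes were drawn there regardless of gene length and number of TSSs. These rates therefore do not cover lists that differ from other genes in length or number of TSSs. A 6-mer planted in 5% of windows was found with odds of 4.56 and an adjusted exact p of 6.05e-20. One planted in 1% of windows was not found (adjusted exact p = 0.977), so rare words can be missed with that number of windows. The simulated windows were fewer than the 8996 summits, so this does not give the power in the real data. They lay at random positions, so the simulation does not cover a difference in G+C between summits and flanks. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

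The number of reads behind each list is unknown, because the lists hold no counts and the replicate lists have the same length by construction.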

Results

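The fru gene of Drosophila melanogaster encodes a family of BTB zinc-finger transcription factors best known for their part in male courtship behaviour. Binding of a GFP-tagged Fru protein was mapped by ChIP-seq in whole wandering larvae, with 3 biological replicates in 1 group and sexes pooled. The question the design addresses is where in the genome the tagged protein is found at this stage. The authors' thresholded list holds 8996 peaks on dm6, with a median width of 460 bp and 3611000 bp covered. Their signal value, a score of the authors' own, has a median of 201.4 and runs from 104.5 to 15085. Replicates 1, 2 and 3 each have a list of 30000 regions, with median signal values of 15.7, 21.4 and 29.2. Depth is unknown, since the lists hold no read counts.

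The strongest peak in the pooled list and in each of the 3 replicates lay at sea, which encodes the mitochondrial citrate carrier (FBgn0037912; 3R 11561834 to 11563275, signal value 15085). Its summit at 11562695 fell 399 bp from a TSS of sea, in sequence shared by the annotated spans of sea and fabp, a fatty acid binding protein gene. The next strongest peak, also in second place in every replicate, lay 60 bp from the TSS of asl, a gene needed for centriole duplication (FBgn0261004; 3R 5606120 to 5607164, signal value 12186). The third lay 85 bp from a TSS of Svil, the fly supervillin gene (FBgn0266696; 3L 2466424 to 2467256, signal value 6759). A peak in an intron of ush, 1367 bp from the TSS of cbt, was the fourth (2L 480557 to 481401, signal value 5923). A promoter peak of Ugalt, the UDP-galactose transporter gene, was the fifth (X 2703651 to 2704152, signal value 5149).

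Among the strongest 25 peaks, 17 had their summit in a promoter, 5 in an intron, 1 in coding sequence, 1 in another exon and 1 between genes. Besides sea, asl, Svil and Ugalt, the promoter peaks lay at Golgin97, CG14100, CG42495, CG1888, Cdc7, larp, PNPase, Hsp27, Chro, Sox14, CG14441, ph-p and mRpL41. Cdc7 encodes a kinase of replication origin firing, Hsp27 a small heat-shock protein, Sox14 a transcription factor induced by ecdysone, and ph-p the Polycomb group protein Polyhomeotic. Intronic peaks lay near cbt, in CG11050, in Lk6, in CG32772, and in CG32486 with CG16753 as the nearest TSS. The coding-sequence peak was in bif (X 11681412 to 11682181), and the peak between genes was 11916 bp from CG13323 (2R 13035041 to 13035599). The remaining peak lay in an exon of lncRNA:CR46035, inside osa. All of these were among the strongest 69 regions of every replicate. The 41 bases centred on the sea summit, in its promoter at 3R 11562675 to 11562715, read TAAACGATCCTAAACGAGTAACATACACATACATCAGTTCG.

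The strongest regions recurred across the 3 replicates. Replicates 1 and 2 shared 6175 of their 8996 strongest regions (68.6%, 95% interval 67.7 to 69.6%), replicates 1 and 3 shared 6203 (69.0%) and replicates 2 and 3 shared 6115 (68.0%). Of the 8996 thresholded peaks, 7041 (78.3%) were present among the strongest regions of replicate 1, 7012 (77.9%) in replicate 2 and 7500 (83.4%) in replicate 3, a mean of 79.9% ± 3.04 (SD, n = 3). All 3 replicates held 5215 peaks (58.0%), and 171 were in none, while 7538 (83.8%) were in the whole lists of all 3. In the strongest decile of the list 98.3% of peaks were present in all 3 replicates, and in the weakest decile 1.22% were, with 41.5, 35.9 and 44.3% in replicates 1, 2 and 3. The thresholded list and the strongest regions of each replicate both end at 8996 regions, so peaks near the end of the list can fall just outside this cut in a replicate.

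Circular shifts gave mean shared shares of 1.39, 1.39 and 1.41% for the 3 pairs (adjusted permutation p = 9.99e-04 for each, one-sided, the smallest that 1000 shifts can give). Across shared regions of the whole lists, Spearman's rho of the signal values was 0.790 for replicates 1 and 2 (15133 regions), 0.787 for 1 and 3 (15286) and 0.777 for 2 and 3 (16188). These correlations are across peaks, which are not independent replicates. The shares depend on how many regions are taken from each replicate. In the whole lists of replicates 1, 2 and 3, 91.9, 93.9 and 95.4% of thresholded peaks were present. With the strongest 4498 regions the mean was 47.0%. All thresholded peaks were sought there too, and they outnumber those 4498 regions. The length of the cut list therefore caps this share, and 47.0% does not show weaker agreement.

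**Figure D1:**
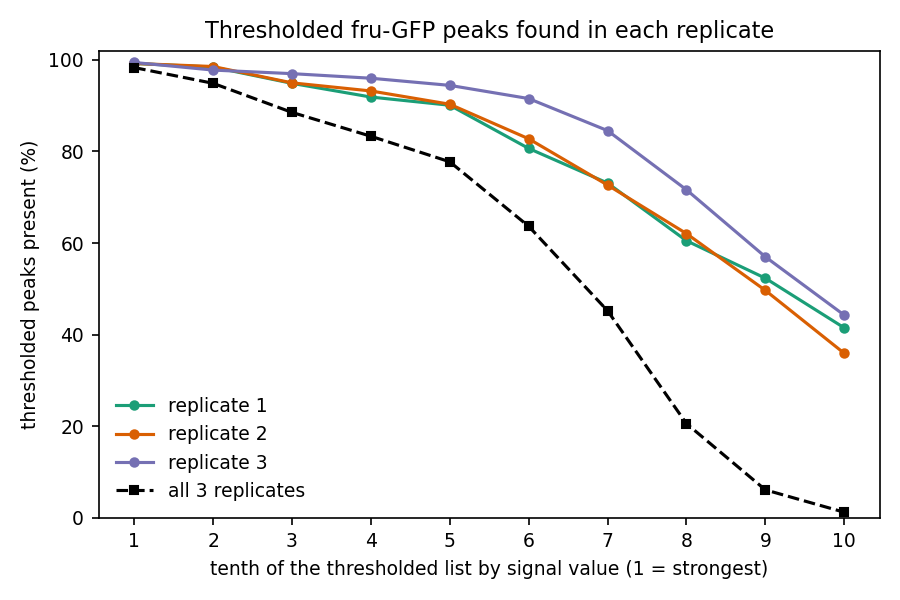
Share of thresholded fru-GFP peaks (y axis, percent) found among the 8996 strongest regions of each replicate and of all 3, by decile of the list from strongest to weakest signal value (x axis). The share in all 3 replicates goes from 98.3% in the strongest decile to 1.22% in the weakest, where each replicate held 35.9 to 44.3%; both kinds of list end at 8996 regions, so peaks of the last deciles can fall just outside the cut.

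Peaks of tagged Fru lay at promoters and in introns, and hardly at all in coding sequence. Promoters, within 500 bp of a TSS, held 3606 of the 8996 summits (40.1%, 95% interval 39.1 to 41.1%), against 13.97% of shifted positions, a 2.87-fold excess. Introns held 3667 (40.8%) and intergenic sequence 1490 (16.6%). Coding sequence outside promoters held 17 summits (0.189%, 95% interval 0.118 to 0.302%), against 14.3% of shifted positions. It held 2.04% of the input regions that did not pass, also below the shifted share. In the strongest regions of each replicate the promoter share averaged 41.4% ± 3.08 and the coding share 0.241% ± 0.0129 (SD, n = 3).

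Against shifted positions, promoters were over-represented and coding sequence, 3' UTRs (69 summits, 0.165 of the shifted share) and intergenic sequence (0.618 of it) under-represented, each with an adjusted permutation p of 0.00350 (raw p = 0.001998, the smallest that 1000 shifts can give). Against input regions that did not pass the threshold, promoters had an odds ratio of 2.30 (adjusted p = 3.32e-204, Fisher's exact test), coding sequence 0.0910 (adjusted p = 2.25e-45), 3' UTRs 0.396 (adjusted p = 9.50e-15), introns 0.769 (adjusted p = 9.98e-25) and intergenic sequence 0.618 (adjusted p = 4.62e-51). The 5' UTRs (57 summits, odds ratio 0.782, adjusted exact p = 0.129) and other exons (90 summits, odds ratio 0.832, adjusted p = 0.138) did not differ by this test. The promoter share was 51.9% in the strongest decile of peaks and 33.4% in the weakest.

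Introns stood 1.05-fold above shifted positions (adjusted permutation p = 0.0308), a call that did not hold in the stricter part of the list (1.00-fold), without replicate 1 (1.04-fold, adjusted p = 0.117) or without replicate 3 (1.04-fold, adjusted p = 0.0769), and that turned to 0.959-fold with promoters of 1000 bp. The 5' UTRs passed the threshold against both backgrounds without replicate 3 (odds ratio 0.652, adjusted exact p = 0.0302; 0.650-fold, adjusted p = 0.0336), in the stricter part of the list, in peaks of all 3 replicates and with promoters of 1000 bp, and other exons passed against shifted positions with promoters of 250 bp (1.46-fold, adjusted p = 0.00466).

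**Figure D2:**
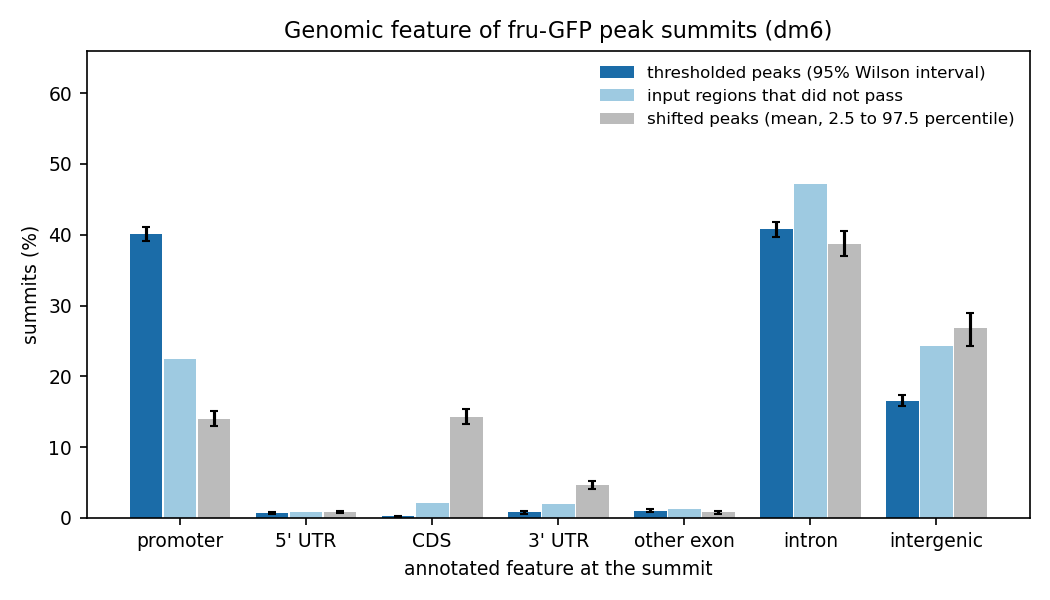
Share of summits (y axis, percent) in each genomic feature (x axis) for thresholded peaks, input regions that did not pass, and circularly shifted positions. Promoters hold 40.1% of thresholded summits against 13.97% of shifted positions, and coding sequence 0.189% against 14.3%.

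The X chromosome carried peaks of tagged Fru about as densely as the large autosome arms. It held 1712 peaks, 72.7 per Mb, beside 68.0 on 2L, 63.2 on 2R, 70.9 on 3L and 64.3 on 3R. The small chromosome 4 held 30 peaks, 22.3 per Mb, and no region of the Y chromosome was in the pooled list. In the strongest regions of each replicate the X share averaged 18.8% ± 0.824 (SD, n = 3).

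Compared with the input regions that did not pass, the X chromosome had an odds ratio of 1.00 (adjusted p = 0.911, Fisher's exact test), chromosome 4 of 0.660 (adjusted p = 0.145), 2L of 0.962 (adjusted p = 0.492), 3L of 0.971 (adjusted p = 0.513) and 3R of 0.993 (adjusted p = 0.911). Peaks on 2R had an odds ratio of 1.1 (adjusted exact p = 0.0329). The 2R call did not hold in peaks of all 3 replicates (1.1, adjusted exact p = 0.0754), without replicate 2 (1.07, adjusted p = 0.171) or on dm3 (1.09, adjusted p = 0.0529), while 3L passed below 1 without replicate 3 (0.911, adjusted p = 0.0303).

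Cytoplasmic ribosomal protein genes formed the gene list with the clearest excess of promoter peaks. Of 93 members, 61 (65.6%, 95% interval 55.5 to 74.5%) had a summit within 500 bp of a TSS, against 24.3% of other protein-coding genes. The strongest lay at RpL14 (place 63 in the pooled list), RpS27 (321), RpL32 (402), RpL34b (424), RpS20 (843) and RpL23A (1033), while RpL10 and RpL10Aa had none. In the strongest regions of each replicate the share was 68.8% ± 3.73 (SD, n = 3). The odds ratio was 5.93 (adjusted p = 1.58e-15, Fisher's exact test), and random lists matched on gene length and number of TSSs gave a mean of 23.9 members (adjusted permutation p = 0.00480, from the smallest raw p that 10000 lists can give, 2.00e-04).

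BTB, disc patterning and axon guidance genes also had promoter peaks more often than other genes. BTB transcription factors, relatives of Fru itself, had a peak at 11 of 16 members (odds ratio 6.76, adjusted exact p = 0.00145), led by the insulator protein gene Cp190, lola, the GAGA factor gene Trl, lolal, fru and ttk, with none at ab and bab1. In the strongest regions of each replicate the share was 72.9% ± 7.22 (SD, n = 3). Imaginal disc patterning genes had one at 22 of 38 (odds ratio 4.24, adjusted exact p = 1.45e-04), led by the EGF ligand gene spi, Dad, dlp, the Dpp receptor gene tkv, ci and tsh, with none at ap and ase. Replicates gave 51.75% ± 11.9 (SD, n = 3), and the odds ratio in replicate 1 was 1.94 (raw exact p = 0.0591). Axon guidance genes had one at 18 of 33 (odds ratio 3.69, adjusted exact p = 0.00145), led by the netrin receptor gene unc-5, Sema1a, Ten-a, Fas2, Lar and Ten-m, with none at beat-Ia and Con. Replicates gave 47.5% ± 9.74 (SD, n = 3), and the odds ratio in replicate 1 was 1.70 (raw exact p = 0.159).

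Ecdysone-response, Notch pathway, and Polycomb and Trithorax genes followed. Ecdysone-response genes had a promoter peak at 14 of 27 members (odds ratio 3.31, adjusted p = 0.00872, Fisher's exact test), led by the ABC transporter gene E23, the early genes Eip74EF and Eip75B, Ldh, Eip63F-1 and vri, with none at crol and Cth. The Notch pathway had one at 12 of 25 (odds ratio 2.84, adjusted exact p = 0.0305), led by the corepressor gene gro, the receptor gene N, E(spl)m7-HLH, numb, E(spl)m3-HLH and neur, with none at Brd and Delta. Polycomb and Trithorax group genes had one at 13 of 27 (odds ratio 2.85, adjusted exact p = 0.0305), led by ph-p, brm, Trl, E(z), ph-d and Sfmbt, with none at ash1 and ash2. Replicate shares were 63.0% ± 6.415 for the ecdysone list, 48.0% ± 4.00 for Notch and 46.9% ± 5.66 for Polycomb and Trithorax (SD, n = 3), the last with an odds ratio of 2.15 in replicate 3 (raw exact p = 0.0685).

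Cuticle genes and digestive enzyme genes had fewer promoter peaks than other genes. None of the 32 cuticle genes had one (95% interval up to 10.7%, adjusted p = 0.00145, Fisher's exact test), Acp1 and Acp65Aa among them. Of 36 digestive enzyme genes 1 did, the trypsin gene zetaTry (odds ratio 0.0873, adjusted exact p = 0.00296), while alphaTry and Amy-d had none. Replicates gave cuticle shares of 1.04% ± 1.80 and digestive enzyme shares of 3.70% ± 1.60 (SD, n = 3).

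Of the 9 calls by Fisher's exact test, only that of ribosomal proteins was also made against random lists matched on gene length and number of TSSs (2.70-fold over other genes, 2.55-fold over matched lists). For 5 lists the matched lists held more genes with a peak than other genes do, and the fold was lower. It went from 2.36 (95% interval 1.72 to 2.94) over other genes to 1.55 over matched lists (1.1 to 2.44 over their central 95%; adjusted permutation p = 0.0636) for the disc list, and from 2.22 (1.55 to 2.86) to 1.499 (1.06 to 2.57; adjusted permutation p = 0.165) for axon guidance. It went from 2.80 (1.81 to 3.50) to 1.37 (0.917 to 2.75; adjusted permutation p = 0.322) for BTB genes, from 1.96 (1.25 to 2.69) to 1.35 (0.867 to 2.60; 0.389) for Polycomb and Trithorax genes, and from 2.11 (1.385 to 2.82) to 1.12 (0.824 to 1.75; 0.841) for ecdysone genes. For the Notch list the fold was about the same, 1.95 (1.22 to 2.71) and 1.98 (1.2 to 6.00), as was the raw p (0.0102 by Fisher's exact test, 0.0106 by permutation), and the call ended in the adjustment over the 24 lists (adjusted permutation p = 0.0636). The cuticle list, with no peak, stood against 7.89 genes expected from other genes and 4.46 in matched lists (central 95% 1 to 8.025; raw permutation p = 0.0140, adjusted 0.0672). The 1 digestive enzyme gene stood against 8.88 and 4.69 (1 to 9; adjusted permutation p = 0.241).

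Against genes with an input region at a TSS the ecdysone odds ratio turned to 0.800, the BTB, Notch, axon guidance, disc, and Polycomb and Trithorax odds ratios were 1.73, 1.08, 1.13, 1.15 and 2.05, and none of these or the cuticle list (adjusted exact p = 0.0684) passed the threshold.

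Keeping only pooled peaks present in both remaining replicates when 1 was left out, and so fewer peaks, ended several calls. The left-out replicate still contributed to the pooled list, so these values show a stricter filter, not an analysis without its reads. The disc odds ratio was 2.28 without replicate 1 (adjusted p = 0.0609, Fisher's exact test) and 1.60 without replicate 2 (0.402), and 2.535 without replicate 3, where the call held (0.0414). For axon guidance it was 1.68 without replicate 2 (0.402) and 1.63 without replicate 3 (0.480), and for the Notch pathway 2.11 without replicate 2 (0.388) and 2.44 without replicate 3 (0.129). Polycomb and Trithorax genes gave 2.19, 2.24 and 2.17 without replicates 1, 2 and 3 (0.206, 0.300 and 0.235), and digestive enzymes 0.128 without replicate 2 (0.0713). In peaks of all 3 replicates none of these 5 lists passed.

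Pan-neural genes and neuropeptide genes did not have more promoter peaks than other genes. Of 27 pan-neural and synaptic genes 3 had a promoter peak, elav (place 178), Csp and Syx1A, and Appl had none. The list did not pass Fisher's exact test (odds ratio 0.383, adjusted p = 0.205), but stood below matched random lists, which gave a mean of 12.1 (adjusted permutation p = 0.00720). Of 29 neuropeptide and hormone genes 3 had one, Nplp1, sNPF and ITP, with none at Akh (odds ratio 0.353, adjusted exact p = 0.169).

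The other lists did not pass the threshold by Fisher's exact test. Sex determination and courtship genes had a promoter peak at 8 of 18 members (odds ratio 2.46, adjusted exact p = 0.140), led by lola, Sxl and fru, with none at dsf. Heat-shock genes had 9 of 22 (odds ratio 2.125, adjusted exact p = 0.169), led by Hsp27 at place 19, Hsp83 and Hsp26, with none at CG4456. Cell cycle and replication genes had 12 of 32 (odds ratio 1.84, adjusted exact p = 0.185), led by Dp, RnrS and aurA, with none at aurB. In the strongest regions of replicates 1, 2 and 3 they had 17, 17 and 11 (46.9% ± 10.8, SD, n = 3), with odds ratios of 3.37, 3.02 and 1.63 (raw exact p = 7.53e-04, 0.00224 and 0.214). That list passed when a summit anywhere in the gene or within 1000 bp counted (odds ratio 2.37, adjusted exact p = 0.0378).

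Among tissue markers, fat body genes had a promoter peak at 7 of 18 (Mtp, Apoltp and Adh first, none at Cyp6a8, odds ratio 1.95, adjusted p = 0.276, Fisher's exact test). In the same order of values, glial genes had one at 6 of 17 (moody, Indy and mdy first, none at alrm, 1.67, 0.527) and muscle genes at 6 of 26 (Tm1, Mef2 and bt first, none at Act57B, 0.919, 1.00). Salivary glue genes had 2 of 12 (Sgs1 and Sgs5, none at Eig71Ee, 0.613, 0.894) and germline genes 4 of 27 (ovo, nanos and gcl first, none at AGO3, 0.5325, 0.521). Circadian genes had 5 of 14 (sgg, vri and cry first, none at CkIIalpha, 1.70, 0.521), neuroblast factors 7 of 26 (brat, grh and Syp first, none at ase, 1.13, 0.894) and immune effectors 7 of 26 (cact, PGRP-LB and pirk first, none at AttA, 1.13, 0.894). Juvenile hormone and steroid biosynthesis genes had 5 of 20 (Jheh1, Kr-h1 and sro first, none at dib, 1.02, 1.00) and Hox and homeobox genes 4 of 21 (tsh, bcd and oc first, none at abd-A, 0.721, 0.894). Several odds ratios changed side of 1 between settings without passing the threshold. Without replicate 1 the Hox, glial, neuroblast and juvenile hormone odds ratios were 1.03, 0.936, 0.569 and 0.485, and the neuroblast and juvenile hormone values stayed below 1 without replicate 2 (0.583 and 0.497) and without replicate 3 (0.5645 and 0.764). Against genes with an input region, fat body and cell cycle genes had 0.628 and 0.943.

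In all, 3436 of 13968 protein-coding genes (24.6%) had a summit at a TSS, and the strongest regions of each replicate gave a mean of 3579.3 ± 218.3 genes (SD, n = 3). Of the 3329 summits at protein-coding TSSs, 937 (28.1%) lay at TSSs of more than 1 gene, so a peak cannot always be assigned to a single gene. The stricter part of the list left 2163 genes. Several genes stand on more than 1 list, among them fru, lola, Trl, vri and tsh.

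**Figure D3:**
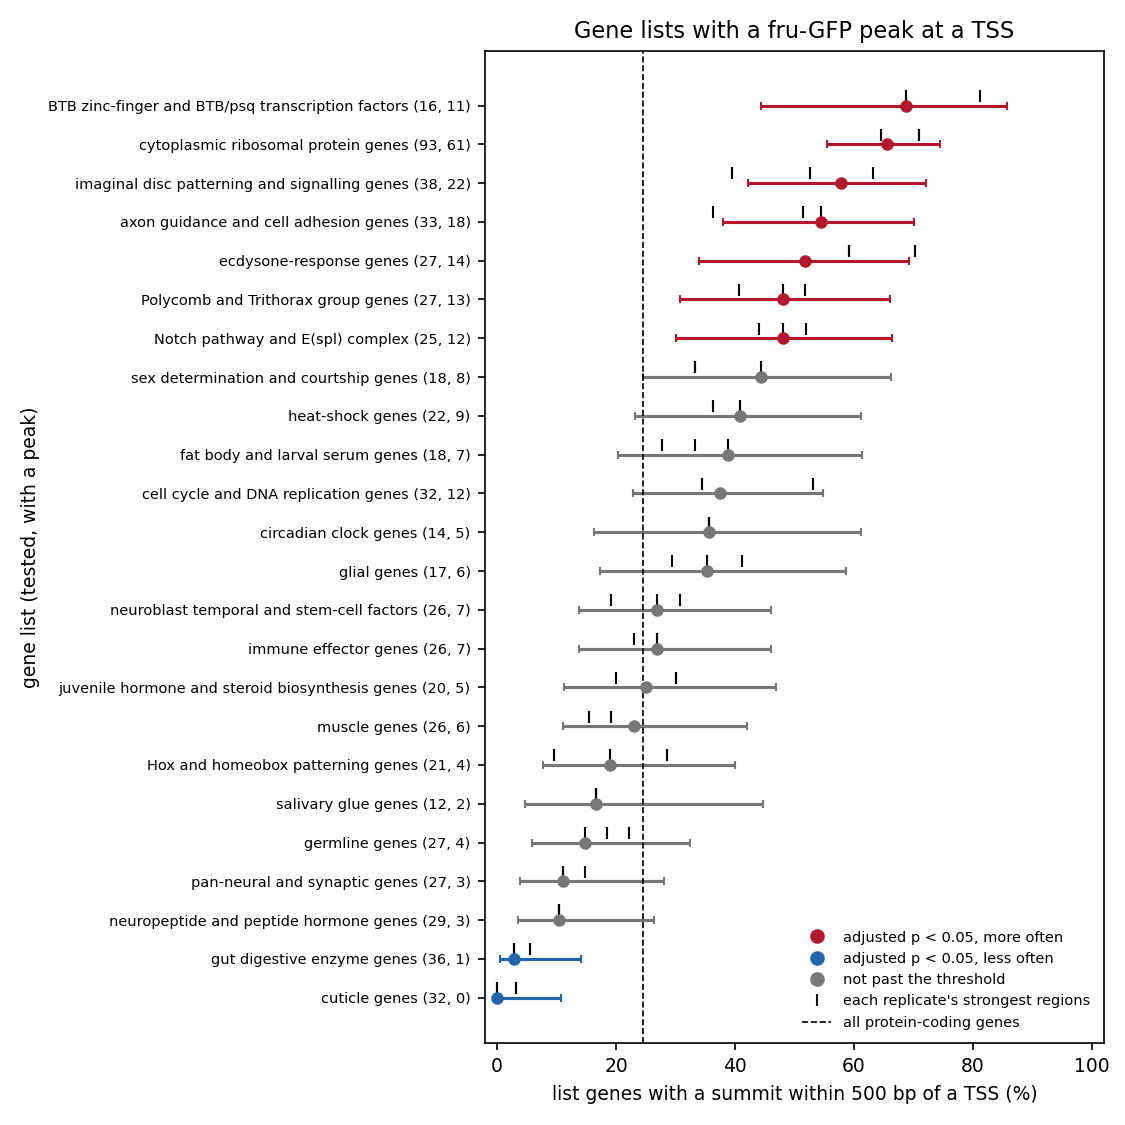
Share of each list's genes with a thresholded summit within 500 bp of a TSS (x axis, percent, points with 95% Wilson intervals) for 24 lists. The y axis gives the numbers tested and with a peak. Ticks show the strongest regions of each replicate, and a dashed line at 24.6% all protein-coding genes. By Fisher's exact test 7 lists lie above other genes, led by ribosomal proteins (65.6%) and BTB factors (68.8%), and 2 below, the cuticle (0 of 32) and digestive enzyme lists.

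The tagged gene fru, a long gene, itself held peaks. Between its end and 5000 bp upstream (FBgn0004652; 3R 18414273 to 18545586, minus strand, 131314 bp) lay 16 thresholded summits, 12 in introns and 4 in promoters. All 16 lay inside the gene, 1.22 per 10 kb, against 64.3 peaks per Mb over 3R. Whether fru holds more than other long genes was not tested. The strongest fru summit, at 18448628, was intronic, 1299 bp from a TSS at 18447329, with a signal value of 1408 and place 165 in the pooled list. In replicates 1, 2 and 3 it held places 100, 233 and 208. The next, at 18436819, 18456403, 18481114 and 18481315, held places 1701, 1724, 1972 and 2357.

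Of the 7 annotated fru TSS positions, 4 had a summit within 500 bp (18438771, 18447329, 18450254 and 18480676). The 3 farthest upstream in the gene, at 18504066, 18506562 and 18545586, had none. Of the 16 summits, 12 had a counterpart within 100 bp in the whole lists of all 3 replicates, and the summit at 18448835, in the same region as the strongest, had none in any. The remaining summits, from 18439104 to 18479507, held places between 5140 and 8616. The bases around the strongest summit, intronic at 3R 18448608 to 18448648, read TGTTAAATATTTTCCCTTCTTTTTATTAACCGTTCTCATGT.

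**Figure D4:**
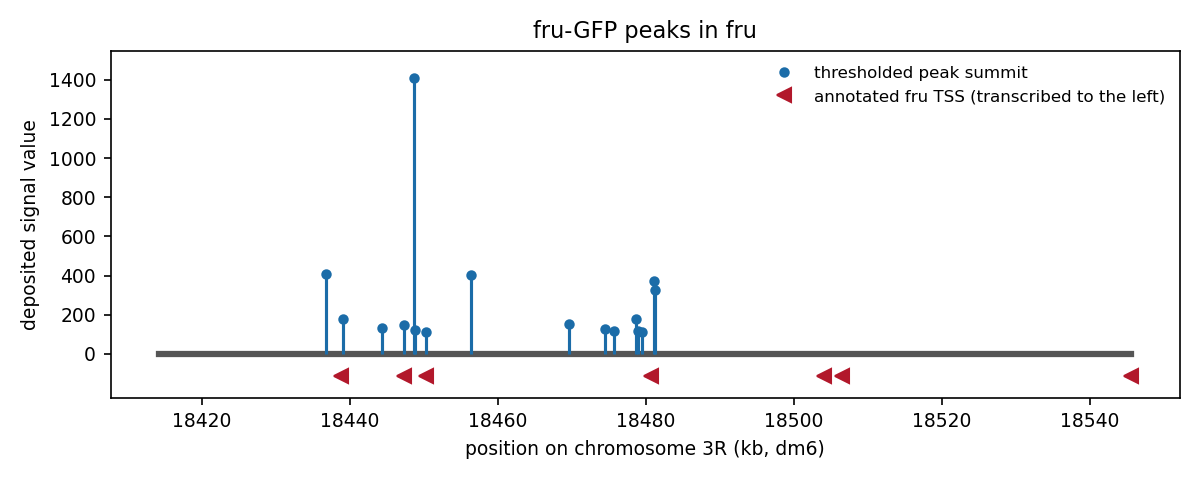
Thresholded fru-GFP summits in fru on 3R (x axis, kb on dm6), with the authors' signal value as the height of each line (y axis) and annotated TSSs as triangles; fru is transcribed to the left. The strongest of the 16 summits has a signal value of 1408, and no summit lies near the 3 TSSs at the right end.

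Other genes of the sex determination and courtship pathway varied. Each gene was searched from its end to 5000 bp upstream. The BTB gene lola had 4 summits inside the gene and 4 upstream, the strongest 328 bp from a TSS, inside the gene at 2R 10541998 (place 349; places 322, 438 and 420 in the replicates). The sex-switch gene Sxl had 3 inside the gene and 1 upstream, 3767 bp from its nearest own TSS, and the strongest lay in an intron at X 7095719 (place 1445). The sex-specific transcription factor gene dsx had 5 inside and 1 upstream, the strongest being the one upstream of the gene at 3R 7969840 (place 3468), and its summit nearest a TSS, at 7963140, had a counterpart within 100 bp in replicate 3 alone. The guidance receptor gene robo1 held 2 (strongest place 6432), tei held 1 (place 8241), and the splicing regulator gene tra held none and no input region.

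Sequence under the summits was AT-rich and held the DREF site TATCGATA, bound by a regulator of housekeeping and replication genes, more often than its surroundings. TATCGATA lay within 50 bp of 109 summits (1.21%, against 0.167% of flanks; odds 8.76, adjusted p = 1.18e-19, exact McNemar test), and GGTCACAC, bound by the core promoter factor M1BP, within 50 bp of 77 (0.856 against 0.245%; odds 3.56, adjusted p = 4.97e-08). The odds of TATCGATA were 4.78, 4.655 and 6.39 without replicates 1, 2 and 3, and those of GGTCACAC 3.00, 3.52 and 5.71, each past the threshold. In the strongest regions of each replicate TATCGATA lay under 1.22% ± 0.357 of summits and in 0.252% ± 0.0251 of flanks (SD, n = 3). The homeodomain core TAATTA (8.39 against 6.16%; odds 1.38, adjusted exact p = 4.97e-08), AAAAAAA (odds 1.39, adjusted p = 1.07e-11) and the Abd-B type word TTTATGA (odds 1.36, adjusted p = 6.41e-04) were also more frequent than in flanks. Against regions that did not pass, TATCGATA (odds ratio 2.37, adjusted p = 6.71e-09, Fisher's exact test), GGTCACAC (1.98, 5.72e-05) and TAATTA (1.13, 0.0251) were more frequent, while AAAAAAA (1.07, 0.133) and TTTATGA (1.06, 0.498) did not pass the threshold. The TAATTA call against these regions ended without replicate 1 (1.13, adjusted exact p = 0.0634) and without replicate 3 (1.11, 0.0973) and with windows of 25 bp (1.14, 0.102), and that of GGTCACAC in the stricter part of the list (1.39, 0.249), while AAAAAAA passed with windows of 100 bp (1.09, 0.0102). G+C content was 36.0% under summits, 43.2% in flanks and 39.4% under regions that did not pass. Promoters held 40.1% of thresholded summits and 22.5% of regions that did not pass. TATCGATA and GGTCACAC were not tested separately inside and outside promoters, so how far promoter location accounts for their excess is not known.

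Of 7 other factor words, 6 were less frequent under summits than in the more G+C-rich flanks, and 1 of these, CACACA, was also less frequent than in regions that did not pass. Against flanks CACACA had odds of 0.680 (adjusted p = 1.42e-12, exact McNemar test), the Zelda word CAGGTAG 0.573 (0.00865), the Su(H) word GTGGGAA 0.630 (0.00248), the E-boxes CACGTG 0.688 (0.0195) and CAGCTG 0.778 (0.00166), and the nuclear receptor word TGACCT 0.730 (0.00341). Against regions that did not pass, CACACA had an odds ratio of 0.779 (adjusted p = 2.78e-07, Fisher's exact test), a call that ended with windows of 100 bp (0.955, 0.285), and CAGGTAG (0.986, 1.00), GTGGGAA (0.790, 0.160), CACGTG (0.867, 0.498), CAGCTG (0.9215, 0.391), TGACCT (1.03, 0.847) and GAGAG (0.989, 0.847) did not pass the threshold. There CAGCTG passed below 1 without replicate 2 (0.826, adjusted exact p = 0.0335), and GAGAG without replicate 2 (0.827, 1.33e-04) and without replicate 3 (0.877, 0.0125), in the stricter part of the list (0.866, 0.0160) and in peaks of all 3 replicates (0.834, 7.43e-04). Against flanks GAGAG, the GAGA factor word, did not pass (odds 0.963, adjusted exact p = 0.411), but passed the threshold below 1 in the stricter part of the list, in peaks of all 3 replicates (0.732), and without replicates 1, 2 and 3 (0.853, 0.761 and 0.787). The CAGGTAG call ended without replicate 1 (0.636, adjusted exact p = 0.0979) and without replicate 2 (0.615, 0.0698), with other window sizes and with flanks 1000 bp away. GTGGGAA lost its call without replicate 2 (0.788, 0.195), TGACCT without replicate 1 (0.794, 0.0784) and without replicate 3 (0.815, 0.117), and GTGGGAA and CACGTG with windows of 25 bp. In peaks of all 3 replicates neither GTGGGAA (0.764) nor TGACCT (0.785) passed.

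Of 2080 6-mers tested, 522 were more frequent under summits than in flanks and 1005 less frequent. The largest odds were those of TACTAA, with 6.66% of summits against 2.89% of flanks (odds 2.39, adjusted p = 4.07e-31, exact McNemar test), and the mean over replicates was 6.39% ± 0.774 under summits and 3.04% ± 0.145 in flanks (SD, n = 3). It was followed by ATATTA (2.37), TTAAAA (2.32), TTTAAA (2.31), ACACTG (2.27), TAGTAA (2.24), CTAGTA (2.23), ATACTA (2.23), AAATAT (2.18) and AATATT (2.17). The lowest odds belonged to CCGGAG (0.248) and ATCCGG (0.273). TACTAA lay within 50 bp of 1 of the strongest 25 summits and of none of the 16 in fru. Summits are on average richer in A and T than their flanks, a difference that this test does not remove.

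On dm3 the authors' thresholded list held 9046 peaks, against 8996 on dm6. The X chromosome had 1750 on dm3 and 1712 on dm6, 2R had 1582 and 1599, and chromosome 4 had 29 and 30. The highest signal value was 15042.5 on dm3 and 15084.6 on dm6. Of the peaks on dm3, 1 lay on 3LHet, a heterochromatic sequence.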

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

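All alternatives named here were planned before the results were seen. A test stayed the same when it kept its direction and its side of the threshold. Shares and correlations stayed the same within the SD of the 3 replicates or pairs, and counts within a fixed fold range. Of 599 recomputed values for 79 results, 467 stayed the same. Of the rest, 57 fell short of the threshold, 24 newly passed it, 9 moved and 42 changed direction. Of those 42, 40 belong to results that had not passed the threshold, and 0 passed it afterwards. By these rules pairwise overlap (18 recomputed values) and the number of 6-mers more frequent under summits stayed the same in every alternative run. The promoter, coding-sequence, 3' UTR and intergenic calls did too. So did the ribosomal protein list and the words TATCGATA, GGTCACAC, TAATTA, AAAAAAA, TTTATGA, CACACA and CAGCTG against flanks. The 6-mer count does not show that the same 6-mers were called. The number of peaks in all 3 replicates (5860 to 6073 when a replicate is left out) can only rise in this way, which says nothing about its stability. The mean share of thresholded peaks present was 86.7% with summits within 250 bp, 73.1% with overlap by 50% of each region, 87.2% with overlap by 1 bp and 93.8% with whole lists. With the strongest 4498 regions it was 47.0%. That value is capped by list length, because the thresholded peaks outnumber those 4498 regions, so it does not show weaker agreement. Correlations in thresholded peaks were 0.775, 0.750 and 0.718. In the stricter part of the list 2163 genes had a promoter peak. The 5' UTR odds ratio was 0.602 and its fold 0.600, the intron fold 1.00, and the odds ratios of axon guidance, disc, and Polycomb and Trithorax genes 1.47, 1.70 and 1.91. GAGAG and GTGGGAA odds were 0.801 and 0.675, and against regions that did not pass GAGAG and GGTCACAC had 0.866 and 1.39. In peaks of all 3 replicates the 5' UTR odds ratio was 0.638 and its fold 0.634, and 2R had 1.1. The Notch, axon guidance, disc, digestive enzyme, and Polycomb and Trithorax odds ratios were 2.36, 1.35, 1.79, 0.143 and 2.11, and the GAGAG, GTGGGAA and TGACCT odds 0.732, 0.764 and 0.785, and GAGAG against regions that did not pass had 0.834. Without each replicate in turn, the ranges were 0.652 to 0.739 for the 5' UTR odds ratio, 0.650 to 0.737 for its fold, 1.04 to 1.08 for the intron fold, 1.07 to 1.11 for 2R and 0.911 to 0.940 for 3L. The lists ranged from 2.11 to 3.44 (Notch), 2.17 to 2.24 (Polycomb and Trithorax), 1.63 to 2.502 (axon guidance), 1.60 to 2.54 (disc) and 0.123 to 0.128 (digestive enzymes). Word odds ranged from 0.532 to 0.636 (CAGGTAG), 0.761 to 0.853 (GAGAG), 0.640 to 0.788 (GTGGGAA) and 0.718 to 0.815 (TGACCT), and against regions that did not pass from 0.827 to 0.931 (GAGAG), 0.826 to 0.899 (CAGCTG) and 1.11 to 1.19 (TAATTA). These last 3 kinds of setting keep fewer peaks, which by itself lowers the power. With promoters of 250 bp the 5' UTR odds ratio was 0.785, the other-exon fold 1.46 and the Notch odds ratio 1.87. With promoters of 1000 bp the 5' UTR values were 0.522 and 0.354, and the intron fold reversed to 0.959. On dm3, 2R had 1.09. Counting a summit in or within 1000 bp of the gene gave cell cycle genes 2.37. Against genes with an input region, ecdysone genes reversed to 0.800, and BTB, Notch, axon guidance, disc, cuticle, and Polycomb and Trithorax genes had 1.73, 1.08, 1.13, 1.15, 0 and 2.05. Folds over matched lists were 1.37 (BTB), 1.12 (ecdysone), 1.98 (Notch), 0.248 (pan-neural), 1.499 (axon guidance), 1.55 (disc), 0 (cuticle), 0.213 (digestive enzymes) and 1.35 (Polycomb and Trithorax). Windows of 25 bp gave CAGGTAG 0.627, CACGTG 0.656 and GTGGGAA 0.717, windows of 100 bp CAGGTAG 0.756, and flanks 1000 bp away CAGGTAG 0.807. Against regions that did not pass, TAATTA no longer passed with 25 bp (1.14), nor CACACA with 100 bp (0.955), and AAAAAAA newly passed with 100 bp (1.09). Results not past the threshold changed side of 1 as follows. In the stricter part, X had 0.9994, neuroblast, glue and immune genes 0.454, 1.09 and 0.712. In peaks of all 3 replicates neuroblast, glue and juvenile hormone genes had 0.652, 1.001 and 0.556. Without each replicate in turn Hox genes ranged from 0.456 to 1.03, neuroblast genes from 0.565 to 0.583, juvenile hormone genes from 0.485 to 0.764 and glial genes from 0.936 to 1.87. Promoters of 250 bp gave juvenile hormone, immune and glial genes 0.701, 0.723 and 0.852, and promoters of 1000 bp neuroblast genes 0.924. With summits in or near the gene, Hox, juvenile hormone and immune genes had 2.02, 0.990 and 0.817. Against genes with an input region, neuroblast, fat body, muscle, cell cycle, juvenile hormone and glial genes had 0.488, 0.628, 1.26, 0.943, 0.628 and 0.943. Neuropeptide genes gave no odds ratio there, since all 3 with an input region had a peak. Folds over matched lists were 0.665 (neuroblast), 1.58 (glue), 0.837 (circadian), 0.890 (juvenile hormone) and 0.872 (glial). GAGAG against flanks had 1.01 with windows of 100 bp and 1.03 with flanks 1000 bp away. Against regions that did not pass, TGACCT had 0.961 with 25 bp, and GAGAG, CAGGTAG, CAGCTG and TTTATGA had 1.07, 1.11, 1.04 and 0.961 with 100 bp. Apart from the smaller number of peaks, the cause was not tested. Depth is unknown, so how far read number limits the weaker peaks of each replicate cannot be given. No paired analysis was possible because there is a single group.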

Other observations

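The gene families, gene classes and words of 8 bases described here, and the tests of AT richness and of core promoter elements, were chosen after the results were seen. The other tests were written down before their results. Of 25 families taken by gene symbol, 3 had a promoter peak more often than other genes, 9 less often, and 13 did not pass the threshold. Mitochondrial ribosomal protein genes had one at 34 of 73 members (46.6%, odds ratio 2.69, adjusted p = 2.13e-04, Fisher's exact test). Rab GTPase genes of membrane traffic had one at 13 of 23 (odds ratio 3.996, adjusted exact p = 0.00327), led by Rab5, Rab8 and Rab39, and Mediator subunit genes at 12 of 25 (odds ratio 2.84, adjusted exact p = 0.0232), led by MED30, MED27 and MED23. Chemosensory genes had almost none: 0 of 60 odorant receptor genes (adjusted exact p = 1.04e-06), 1 of 60 gustatory and 1 of 60 ionotropic receptor genes (8.14e-06 each) and 2 of 51 odorant-binding protein genes (4.51e-04). A promoter peak was also rare at cuticle protein genes of the RR class (1 of 70, 1.04e-06), seminal fluid protein genes (1 of 46, 2.13e-04), defective proboscis extension response genes (1 of 32, 0.00834) and Jonah protease genes (0 of 16, 0.0365), each by exact test, and 9 of 81 cytochrome P450 genes had one (11.1%, odds ratio 0.3815, adjusted exact p = 0.0101). Proteasome subunit genes (12 of 48) and cytoplasmic translation initiation factor genes (12 of 44) were among those that did not pass. Matched random lists were not run for these families.

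Several genes held many thresholded summits. The cell adhesion gene kirre held 33 in 394149 bp, sbb 29, CG1677 28, the gene of the DNA dioxygenase homologue Tet 27 and the ecdysone-induced receptor gene Eip75B 26. Relative to length, Mnt, the gene of a partner of Max, held 6.70 per 10 kb and tara 5.77, against 1.22 in fru. Of the genes not coding for protein, 8 of 32 snRNA genes, 15 of 269 snoRNA genes and 0 of 99 rRNA genes had a summit within 500 bp of the start. Among 32896 words of 8 bases, 1626 were more frequent under summits than in flanks. Only words found under at least 100 summits and not in the flank were ranked by odds. Of these, CACTGAGA lay under 1.14% of summits against 0.156% of flanks (odds 7.14, adjusted p = 8.55e-15, exact McNemar test) and CAACACTG under 1.33 against 0.267% (odds 5.09, adjusted p = 9.08e-14), beside the DREF word TATCGATA (odds 8.76). The words were picked and tested on the same summits, so their odds can be too high.

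The first pattern is the near absence of summits from coding sequence (0.189%). Input regions that did not pass also held few there (2.04%, against 14.3% of shifted positions), so part of it is shared with those regions. Libraries that favour AT-rich DNA are unlikely to be the whole cause, because random positions matched to the summits on G+C had a coding share of 7.43%, above the upper limit of 0.302%. Counting coding bases near a TSS as promoter is not the whole cause either, since without that priority 0.5002% of summits lay on coding bases, against 17.4% of shifted positions (16.2 to 18.9%). No biological explanation was tested, and the control was not analysed here.

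The second pattern is the 6-mers under summits. AT richness may account for ATATTA, which had the largest odds on 2L, 2R and 3L, since its odds on 3R, X and 4 were 2.28 with an interval (95%, 1.97 to 2.64) that holds the upper end of the central 95% of the other 6-mers without G or C (2.30), so it cannot be told apart from a sequence preference for this word. For AGGGTA, which stood farthest above words of its own G+C class, the odds on 3R, X and 4 were 1.71 (1.29 to 2.30). The other 639 6-mers with 3 G or C had a median of 0.849, and their central 95% reached up to 1.49. The interval of AGGGTA lies above 1 but holds that upper end. By the criterion used for ATATTA it therefore cannot be told apart from words of its class either. A criterion of direction, odds above 1 against a class median below 1, would set AGGGTA apart, but it was added after the values were seen. For AGGGTA a core promoter element is not the whole cause, since its odds outside promoters on 3R, X and 4 were 1.82 (1.28 to 2.62). Those of ATATTA were 2.35 (1.95 to 2.84). The other 6-mers without G or C had a median of 1.80 over all summits of these chromosomes, so odds above 1 cannot decide this for ATATTA. No biological explanation was tested, and no word here is shown to be a site of Fru.

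The third pattern is the ribosomal protein promoters (65.6%, lower limit 55.5%). Of 290 tRNA genes, 11.7% had a summit within 500 bp (up to 15.9%), below that lower limit. No expression levels were used and tRNA genes do not code for protein. This share therefore cannot decide whether strong transcription of protein-coding genes is the cause. As a test of expression in every cell, 22.6% of 84 oxidative phosphorylation genes had a promoter peak (up to 32.7%), below the lower limit of the ribosomal protein share. Proteasome subunit genes had 25% (up to 38.8%) and initiation factor genes 27.3% (up to 41.9%), also below it. However, mitochondrial ribosomal protein (46.6%, up to 57.9%) and Mediator genes (48.0%, up to 66.5%) reach that limit. The families thus differed. They were taken by gene symbol and their expression was not checked, so these shares cannot decide whether expression in every cell is the cause. Peaks of neighbouring genes are not the whole cause, because among genes with no other TSS within 1000 bp ribosomal proteins had 9 of 21 (odds ratio 3.86, p = 0.00368, Fisher's exact test). Signal that any GFP-tagged protein or the antibody would give at open promoters stays open, since the control was not analysed here, and no biological explanation was tested.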
